A study of Mus musculus with 10 samples.

How the data were processed

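The series holds 10 RNA-seq libraries of splenic germinal center B cells from immunized C57BL/6 mice. Per the labels, cells were enriched with PNA beads, RNA was isolated with a column kit for small samples, and libraries were made with the KAPA RNA HyperPrep kit after ribosomal RNA depletion. The deposited table gives whole-number read counts per gene, not normalized, for 55421 genes. The submitters' processing notes name FastQC, STAR, Subread, featureCounts, R 4.2.1 and the mm10 genome, with no order or settings. The strand setting, the treatment of reads that match several places, the overlap rules and the annotation release are not given in the sources used here, so genes that overlap, antisense genes and near-identical copies have uncertain counts. The deposited table also gives a length per gene, which was used only in the check of length. Every gene identifier with a version that was found in GENCODE M21 (54673 of 54673) had the chromosome, start and end given there, and coordinates are on mm10. Of the identifiers, 54587 were matched to a symbol with their version, 567 without it, and 267 were not matched and kept their identifier.

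Groups were taken from the sample titles: WT CB (n = 3), WT CC (n = 3), HOMO CB (n = 2) and HOMO CC (n = 2). The HOMO columns of the count table are numbered 2 and 3, while the HOMO titles are numbered 1 and 2. A HOMO column was therefore assigned to its group only, keeps the number of the table as a name, and has no pairing. Libraries of a group were compared for duplicates by a chi-square test over genes with at least 20 reads summed over both. The statistic per degree of freedom lay between 4.14 and 81.4, so all pairs differed by more than sampling noise.

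The tests, the samples in each fit, 32 gene lists (21 of biological processes and the others of cell types, sex-linked genes and mitochondrial genes) and the rule for naming genes were fixed before the data were examined. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 16596, and libraries were scaled with TMM factors. A negative binomial model of the 4 group means was fitted to all 10 libraries, so that the groups share 1 estimate of the spread, and tested with edgeR's robust quasi-likelihood F-test in R 4.3.3. The 5 contrasts were HOMO against WT in CB and in CC, CC against CB in WT and in HOMO, and the interaction. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. The common biological coefficient of variation was 23.1%. CPM values are TMM-scaled, log2 changes are those of the fit, and SEs were derived from the log2 change and its F statistic. Lists were tested two-sided with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 32 lists of a contrast, and again with an estimated correlation and with fry. Of 928 list members 926 were in the table and 858 were tested. Some genes are in several lists.

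The text names Pbrm1, Arid2, Brd7, Phf10 and Smarca4. For each comparison of 2 groups it takes up to 8 genes with the largest rise and 8 with the largest fall that passed, reached 5 CPM in the higher group, did not overlap between the libraries and had a symbol other than a predicted gene, pseudogene or receptor segment. For the interaction it takes the 4 genes with the smallest p, since none passed. For a list it takes up to 4 members with the smallest p among those that passed, or else 2 members with values only. Members of cell type, sex-linked and mitochondrial lists are given as levels. A result of 1 gene that this rule takes is not reported here.

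The WT replicate numbers were checked for pairing before the fits were compared. Across 8805 genes with an average log2 CPM of at least 3, deviations from the group means of same-numbered WT CB and CC libraries correlated with r = 0.301, 0.426 and 0.436, while those of different numbers ranged from -0.411 to 0.278. The WT numbers were therefore taken to pair the libraries, as a result of the data and not of a label, and fits with the WT number as a block were run for the contrasts between fractions and the interaction. A fit with the WT number as a random block (correlation 0.307) was run for all 5 contrasts.

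The steps were tested on simulated counts drawn from the means and library sizes of the real samples, with 200 genes changed. The changed genes were drawn from those with a mean of at least 5 CPM, so the shares recovered do not cover lower genes. At folds of 1.5, 2 and 4 the share recovered was 29.9%, 74.6% and 97% for HOMO against WT in CB (16016 genes), 16.4%, 82.1% and 93.9% in CC (16028 genes), 35.8%, 76.1% and 98.5% for CC against CB in WT (15988 genes) and 22.4%, 61.2% and 95.5% in HOMO (15998 genes). False calls numbered 11, 4, 9 and 5. Apart from the changed genes, each gene had the same mean level in all simulated libraries. These counts held neither a GC content trend nor a difference between WT numbers. The shares recovered and the false calls therefore do not show what such differences between libraries would give. The counting error of a level follows its count, and the total lay between 9954006 and 27091509 counts in CC and between 26372234 and 67625110 in CB.

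Alternatives fixed before the data were examined were other scalings, DESeq2 1.42.0, limma-voom, other low-count filters, only the groups compared, a test against a fold of 1.2, no receptor segment genes, replicate blocks and leaving out each library. Chosen after seeing the data were offsets for GC content and length (lowess span 0.3), the blocks restricted to the WT numbers, Xist or the ribosomal RNA locus share as a covariate, removal of the 2 genes of that locus, and fits without both libraries of a WT number, without WT numbers 1 and 2, or without WT CC libraries 1 and 2. GC content was available for 16576 of the genes tested (99.88%).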

Results

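RNA was sequenced from splenic germinal center B cells of C57BL/6 mice, the B cells that mutate their antibody genes and are selected for antigen binding after immunization. The cells were enriched on day 10 after immunization with magnetic beads for the lectin PNA, and ribosomal RNA was depleted during library preparation. The mice were labelled Pbrm1+/+ (WT) or Pbrm1-/- (HOMO), and each genotype gave a fraction labelled CB and a fraction labelled CC. The labels do not spell out CB and CC, and the title of the study speaks of the fate of centrocytes. Pbrm1 encodes a bromodomain subunit of PBAF, a form of the SWI/SNF chromatin remodelling complex, and Smarca4 encodes an ATPase of that complex. The 10 libraries comprised 3 WT CB, 3 WT CC, 2 HOMO CB and 2 HOMO CC libraries. The total counts were 26372234, 30412732 and 61627968 in WT CB libraries 1, 2 and 3 and 27091509, 19946853 and 13662538 in WT CC libraries 1, 2 and 3. The HOMO libraries carry the numbers 2 and 3 in the count table. They held 27034386 and 67625110 counts in CB and 15514361 and 9954006 in CC. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these libraries, which may be technical in part.

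The level of Pbrm1, the targeted gene (ENSMUSG00000042323.17, mm10 chromosome 14, 31019138 to 31121592), was lower in both HOMO libraries than in all 3 WT libraries of each fraction. Its mean after TMM scaling was 313 ± 5.23 CPM (SD, n = 3) in WT CB and 171 ± 9.83 CPM (n = 2) in HOMO CB. It was 243 ± 6.54 CPM (n = 3) in WT CC and 151 ± 1.02 CPM (n = 2) in HOMO CC. Pbrm1 fell in CB, with a log2 change of -0.88 (SE 0.087, edgeR adjusted p = 0.00954), and its log2 change in CC was -0.68 (SE 0.087, edgeR adjusted p = 0.0564). The labels do not give the change made in the gene and the counts cover all of it, so transcripts that lack only a deleted part would still be counted. These values do not show whether Pbrm1 function was lost. The columns of the count table carry the letters AID beside the name of the gene, which the labels do not explain. Whether the allele is the one that the label Pbrm1-/- names was not settled here. Among the other PBAF subunits, the log2 change in CB and CC was 0.32 (SE 0.12) and 0.38 (SE 0.12) for Arid2, -0.03 and -0.08 for Brd7 and 0.15 and 0.11 for Phf10. For the ATPase Smarca4 it was -0.20 and -0.19, and none of these 4 genes passed in either fraction by edgeR (adjusted p of at least 0.15). Arid2 passed without WT CB library 3 (0.41, adjusted p = 0.0326) in CB and without WT CC library 3 (0.49, adjusted p = 0.0177) in CC, and Smarca4 in CB without WT CB library 3 (-0.31, adjusted p = 0.0472), all by edgeR. Over all alternatives the adjusted p of Arid2 ranged from 0.00025 to 1 in CB and from 8.26e-05 to 0.928 in CC, and that of Smarca4 from 0.00512 to 1 in CB and from 0.0273 (without both libraries of WT number 3) to 0.996 in CC. Brd7 passed in CC with the GC content offset without WT number 3 (-0.24, adjusted p = 0.0112), and Phf10 in CB without WT numbers 1 and 2 (0.37, adjusted p = 0.0276). The Pbrm1 call in CB was lost without WT CB library 1 (adjusted p = 0.111), HOMO CB library 2 (0.154) or 3 (0.537), or HOMO CC library 2 (0.069) or 3 (0.0716). It was also lost with only the groups compared (adjusted p = 0.233) and without both libraries of WT number 1 (0.118) or 2 (0.152). Pbrm1 passed in CC without WT CB library 3 (adjusted p = 0.0122), WT CC library 3 (0.00243) or both (1.24e-05), and without WT numbers 1 and 2 (0.000125). It also passed there with DESeq2, with no low-count filter (5.64e-05) or a stricter one (0.0396), with the GC content offset (0.00305, and 4.23e-07 without WT number 3) or that for GC content and length (0.00461), and with Xist as a covariate (0.0356). Its log2 change was negative in both fractions under all alternatives run. Over these the adjusted p ranged from 8.84e-23 (DESeq2) to 0.537 in CB and from 8.7e-12 (DESeq2) to 0.55 in CC.

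**Figure D1:**
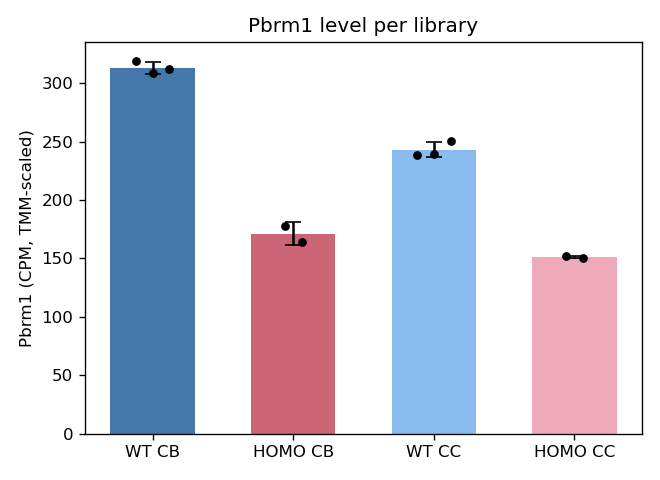
Pbrm1 level in CPM (TMM-scaled) in the 4 groups. Bars are group means, error bars are the SD and points are single libraries, with n = 3 for WT and n = 2 for HOMO. The HOMO CB libraries lie at 177.8 and 163.9 CPM and the lowest WT CB library at 308.7 CPM.

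The libraries also differed in properties that the groups do not define. Xist, the X-inactivation RNA made in female cells, was at 467.2 and 72.49 CPM in WT CB libraries 1 and 2, at 2668 CPM in WT CB library 3, and at 2022 and 2884 CPM in HOMO CB libraries 2 and 3. The WT CC libraries were at 707.7, 84.46 and 2386 CPM and the HOMO CC libraries at 2292 and 2746 CPM. The Y-linked gene Ddx3y lay between 35.2 and 103.5 CPM over the 10 libraries, so each library held transcripts of both Xist and a Y-linked gene. In libraries 1, 2 and 3 it was at 79.62, 103.5 and 40.12 CPM in WT CB and at 85.93, 97.35 and 39.25 CPM in WT CC. This order is opposite to that of Xist in both fractions, which argues against the WT numbers being repeats of 1 sample. Listed macrophage genes summed to 1532, 607.1 and 323.7 CPM in WT CC libraries 1, 2 and 3, against 271.5 and 251.6 CPM in HOMO CC and between 281.5 and 415.9 CPM in CB. Of these sums Apoe alone gave between 212 and 399 CPM in each library. Listed neutrophil genes summed to 181.9 and 163.9 CPM in HOMO library 2 of CB and CC, 10.65 and 25.34 CPM in HOMO library 3, 18.42 and 26.82 CPM in WT library 3, and at most 6.86 CPM in WT libraries 1 and 2. Listed mitochondrially encoded genes summed to 27330, 16050 and 9347 CPM in WT CC and to 9354 and 9077 CPM in HOMO CC. The 2 genes over the ribosomal RNA locus took 22.7%, 19.0% and 13.5% of the counts in WT CC, 10.8% and 11.2% in HOMO CC, and between 8.72% and 11.9% in CB. The deviation of each library from the gene means followed GC content across 8802 genes, which are not independent replicates, with a Spearman rho of 0.15, 0.248 and -0.457 in WT CB libraries 1, 2 and 3 and of -0.632 and -0.605 in HOMO CB. It was 0.431, 0.552 and 0.152 in WT CC and -0.173 and -0.222 in HOMO CC.

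**Figure D2:**
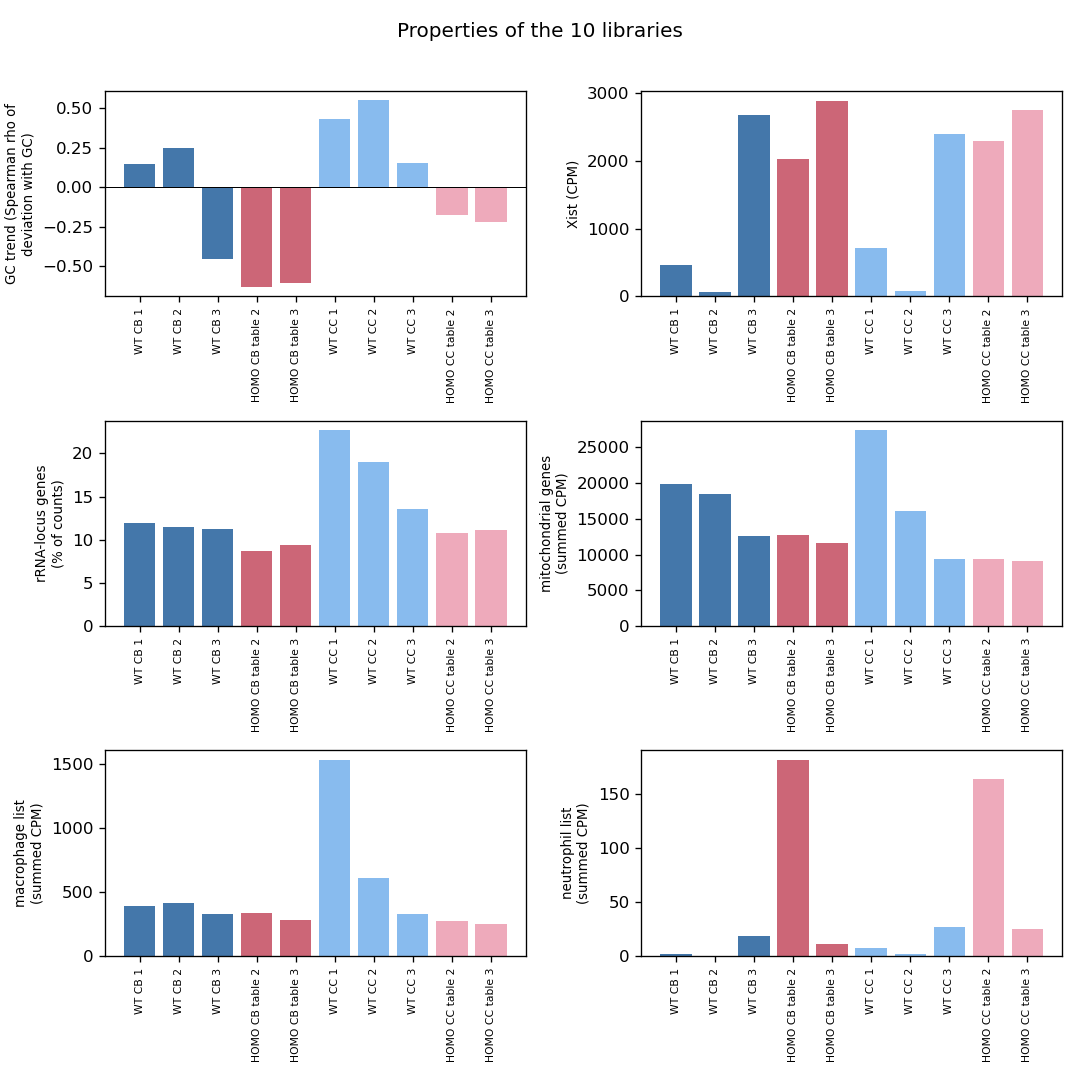
Properties of the 10 libraries, 1 bar per library, with WT in blue and HOMO in red. The panels show the Spearman rho of the deviation of a library from the gene means with GC content, Xist in CPM, the percent of counts on the 2 genes over the ribosomal RNA locus, and the summed CPM of mitochondrial, macrophage and neutrophil genes. The macrophage sum is highest in WT CC library 1 (1532 CPM) and the neutrophil sum in HOMO CB library 2 (181.9 CPM).

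The CC and CB fractions were first compared within WT, which sets them side by side and does not follow cells from one to the other. The word stage is used for these fractions, although the labels do not name them as stages. In CC, genes of light zone activation rose together: 21 of the 27 tested passed upwards and 0 downwards (23 and 0 adjusted over the list alone), with a median log2 change of 1.13. Cd83, an activation marker, went from 142 ± 10.7 to 353 ± 36.4 CPM (log2 1.31, SE 0.11, edgeR adjusted p = 4.7e-05, n = 3 and 3). Il4i1, an amino acid oxidase, rose by log2 2.29 (SE 0.19) and the transcription factor gene Myc by log2 1.13 (SE 0.089). Targets of NF-kB and CD40 rose in 21 of 30 cases and fell in 0 (25 and 0 adjusted over the list alone), with a median of 0.74. Among them were the NF-kB subunit genes Nfkb2 (log2 1.29, SE 0.099) and Relb (1.30, SE 0.12). Both lists passed camera with its preset correlation (adjusted p = 3e-24 and 2.97e-18) and with an estimated correlation (adjusted p = 0.00836 for each).

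Dark zone genes other than cell cycle genes fell in 10 of 15 cases and rose in 1 (12 and 2 adjusted over the list alone), with a median log2 change of -0.66. The chemokine receptor gene Cxcr4, which holds cells in the dark zone, went from 312 ± 61.9 to 84.1 ± 13.7 CPM (log2 -1.89, SE 0.16, edgeR adjusted p = 3.81e-05). The log2 change was -2.47 (SE 0.15) for Gcsam, a regulator of germinal center B cell motility, -1.67 (SE 0.12) for Polh, an error-prone polymerase of somatic hypermutation, and -1.51 (SE 0.12) for the DNA end-joining ligase gene Lig4. The gene that rose was Sema4b (log2 0.46), which was singled out after its values were seen. The list passed camera with an estimated correlation (adjusted p = 0.0404), but not in the fit with the WT replicate number as a block (adjusted p = 0.195 with an estimated correlation). Genes of the G2 and M phases fell in 54 of 55 cases and rose in 0 (55 and 0 adjusted over the list alone), with a median of -0.94. Examples were the phosphatase gene Cdc25b, from 423 ± 78.1 to 164 ± 9.37 CPM (log2 -1.37, SE 0.13), the kinetochore gene Cenpf (-1.23, SE 0.12) and the spindle gene Hmmr (-1.34, SE 0.11). The camera call of the G2 and M phase list at the preset correlation (adjusted p = 9.7e-55) was lost with an estimated correlation (adjusted p = 0.0876 with an estimated correlation).

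Genes of MYC targets and ribosome biogenesis rose in 24 of 50 cases and fell in 0 (28 and 0 adjusted over the list alone), with a median log2 change of 0.34 (camera adjusted p = 3.55e-11, and adjusted p = 0.325 with an estimated correlation). Srm, the spermidine synthase gene, rose by log2 1.17 (SE 0.12) and Polr1b, a subunit gene of RNA polymerase I, by log2 1.05 (SE 0.098). Nuclear genes of oxidative phosphorylation fell in 36 of 73 cases and rose in 0 (39 and 0 adjusted over the list alone), with a median of -0.44. Camera gave adjusted p = 7.56e-10 (adjusted p = 0.585 with an estimated correlation). Ribosomal protein genes fell in 16 of 80 cases and rose in 1, Rps10 (13 and 1 adjusted over the list alone), with a median of -0.27. Camera gave adjusted p = 5.28e-05 (adjusted p = 0.647 with an estimated correlation), and without WT numbers 1 and 2, which leaves 1 WT library per fraction, the median was 0.051 and the list did not pass (0.118). Many ribosomal protein genes have near-identical pseudogenes that could share their reads, as could Bcl2a1a, Bcl2a1b and Bcl2a1d among the light zone genes. Genes of germinal center identity moved both ways, with 12 of 27 lower and 5 higher (14 and 6 adjusted over the list alone; camera adjusted p = 0.0106, and adjusted p = 0.179 with an estimated correlation). Pou2af1, a coactivator of B cell transcription, fell by 1.33 (SE 0.13) and Lmo2, a transcription cofactor gene, rose by 1.28 (SE 0.18). Genes of MHC class II presentation rose in 5 of 17 cases and fell in 1 (7 and 1 adjusted over the list alone), with a median of 0.27. The list passed camera (adjusted p = 0.00355, and adjusted p = 0.585 with an estimated correlation), but not without WT CB library 3 (0.0737). Smarca4 went from 955 ± 129 to 445 ± 29.2 CPM (log2 -1.10, SE 0.11, edgeR adjusted p = 0.000108), and Pbrm1 fell by 0.37 (SE 0.076, edgeR adjusted p = 0.00609).

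Of 16596 genes tested, 1917 rose and 2048 fell in WT CC (edgeR quasi-likelihood test, adjusted p under 0.05). With upper-quartile scaling the split was 2351 and 1599, or 59.5% higher against 48.3%. The total of 3965 was 2099 without WT CB library 1, 2442 without WT CB library 2, 2485 without WT CC library 1, 2502 without WT CC library 2 and 858 without both of these WT CC libraries. It was 656 with the share of counts on the ribosomal RNA locus as a covariate, 2340 with only the groups compared and 2134 against a fold of 1.2. It was 1010, 1243 and 7404 without both libraries of WT number 1, 2 or 3, and 2421 without WT numbers 1 and 2. The largest falls among expressed genes included Reln, a secreted glycoprotein gene, from 87.6 ± 3.05 to 10.4 ± 1.8 CPM (log2 -3.09, SE 0.14), and the receptor genes Ret (-3.57, SE 0.29) and Lgr5 (-2.89, SE 0.14). The log2 change was -4.74 (SE 0.53) for Ccdc190, which was at 0.0702 to 0.518 CPM in WT CC, -4.37 (SE 0.30) for Tgfa, -4.16 (SE 0.39) for Scn11a, -3.17 (SE 0.31) for Gcnt3 and -2.74 (SE 0.23) for Zkscan16. The largest rises were in genes near 0 CPM in CB that followed the macrophage sum. Of these, Mertk, a receptor for apoptotic cells, stood at 61.7, 12.6 and 0.772 CPM in WT CC libraries 1, 2 and 3 and at no more than 0.552 CPM in WT CB, and C6, Fcna, Gfra2, Itgad, Paqr9, Ptprm and Wdfy3 had the same order of libraries. By edgeR the calls of Itgad, Mertk and Wdfy3 were lost without any 1 of the WT CB libraries (adjusted p up to 0.0807, 0.0969 and 0.0768) and those of Fcna and Gfra2 without WT CB library 2 (0.0635 and 0.0584). With the WT replicate number as a random block in limma-voom, none of these 8 genes passed (adjusted p from 0.121 to 0.254). Of 22 macrophage genes tested, 16 rose and 0 fell (18 and 0 adjusted over the list alone), and the list passed camera (adjusted p = 4.87e-07) but not with an estimated correlation (adjusted p = 0.559). Of 7 dendritic cell genes 4 rose and 0 fell (4 and 0 adjusted over the list alone). The list had a median of 1.01 and passed camera (adjusted p = 0.0259, and adjusted p = 0.361 with an estimated correlation). It did not pass without WT CB library 3 (0.865, adjusted p = 0.0795), without both libraries of WT number 3 (1.97, 0.108) or with the GC content offset (0.816, 0.0529).

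The same comparison was made between the CC and CB libraries labelled HOMO. Light zone genes rose in 16 of 27 cases and fell in 0 (21 and 0 adjusted over the list alone), with a median log2 change of 1.17. Cd83 went from 142 ± 21.2 to 387 ± 2.74 CPM (log2 1.45, SE 0.14, edgeR adjusted p = 0.000422, n = 2 and 2), Myc rose by 1.18 (SE 0.11), Il4i1 by 2.08 (SE 0.23) and Egr1, an immediate early gene, by 1.31 (SE 0.17). NF-kB and CD40 targets rose in 13 of 30 cases and fell in 0 (18 and 0 adjusted over the list alone), with a median of 0.73, and Nfkb2 (1.15, SE 0.12) and Relb (1.05, SE 0.14) were again among them. Both lists passed camera with an estimated correlation (adjusted p = 0.00374 for each). Dark zone genes fell in 8 of 15 cases and rose in 0 (10 and 2 adjusted over the list alone; median -0.54), and the camera call at the preset correlation (adjusted p = 6.44e-14) was lost with an estimated one (adjusted p = 0.0502 with an estimated correlation). Cxcr4 went from 291 ± 12.1 to 108 ± 3.58 CPM (log2 -1.43, SE 0.19, edgeR adjusted p = 0.00158), and the log2 change was -2.32 (SE 0.18) for Gcsam, -1.36 (SE 0.14) for Polh and -1.29 (SE 0.14) for Lig4. G2 and M phase genes fell in 41 of 55 cases and rose in 0 (53 and 0 adjusted over the list alone; median -0.72), with camera adjusted p = 1.48e-52 and adjusted p = 0.081 with an estimated correlation. The log2 change was -1.35 (SE 0.15) for Cdc25b, -1.34 (SE 0.15) for Cenpf and -1.21 (SE 0.14) for Hmmr.

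MYC target and ribosome biogenesis genes rose in 15 of 50 cases in HOMO CC and fell in 0 (27 and 0 adjusted over the list alone; median 0.37; camera adjusted p = 1.76e-18, and adjusted p = 0.13 with an estimated correlation). Among oxidative phosphorylation genes 0 of 73 passed in either direction (0 adjusted over the list alone), with a median of -0.20 and camera adjusted p = 0.00458 (adjusted p = 0.74 with an estimated correlation). Ribosomal protein genes had 0 of 80 passing (0 adjusted over the list alone) and a median of -0.04, which was above 0 with another scaling, and did not pass camera (adjusted p = 0.674). MHC class II genes rose in 5 of 17 cases, as in WT, and fell in 0 (10 and 1 adjusted over the list alone; median 0.44; camera adjusted p = 2.57e-06, and adjusted p = 0.358 with an estimated correlation). Smarca4 went from 829 ± 60.5 to 392 ± 16.4 CPM (log2 -1.08, SE 0.14, edgeR adjusted p = 0.00119), while the log2 change of Pbrm1 was -0.18 (SE 0.094, edgeR adjusted p = 0.348). The largest falls included Ret (-3.87, SE 0.38), Tgfa (-3.63, SE 0.36), Scn8a (-3.10, SE 0.34), Gcnt3 (-2.94, SE 0.40), Tifa (-2.84, SE 0.29), Zkscan16 (-2.73, SE 0.28), Dnase1 (-2.58, SE 0.30) and Reln (-2.55, SE 0.17). The largest rises that held without any single library were those of the cytokine subunit gene Ebi3 (2.39, SE 0.32) and of Trabd2b (2.48, SE 0.24). Without HOMO CB library 3 the calls of Ppfia4 (2.80, edgeR adjusted p = 0.0693 then), Tnfrsf8 (2.76, 0.0566), Shank1 (2.69, 0.0532) and Plscr1 (2.27, 0.0516) were lost. Those of Fcrl5 (3.37) and the cyclin gene Ccnd2 (2.94) were lost without any 1 of the 4 HOMO libraries, with adjusted p up to 0.292 and 0.257, and that of Fcrl5 also without WT CB library 1 (0.0517) or 2 (0.0713). Marker lists shifted between the HOMO fractions as well. The macrophage list had a median of 1.94 (18 of 22 positive, camera adjusted p = 0.00258, and adjusted p = 0.595 with an estimated correlation). Of its genes 0 passed (0 adjusted over the list alone), and their summed level was 337.4 and 281.5 CPM in HOMO CB and 271.5 and 251.6 CPM in HOMO CC. Most of this sum was Apoe, at 304 and 265 CPM in HOMO CB and 227 and 212 CPM in HOMO CC, so the sum does not show how the other genes moved. Naive follicular B cell genes rose in 3 of 20 cases and fell in 1 (4 and 1 adjusted over the list alone; median 0.31; camera adjusted p = 0.00398, and adjusted p = 0.455 with an estimated correlation). The mitochondrially encoded genes had a median of -0.64 (12 of 12 negative, camera adjusted p = 0.0397, and adjusted p = 0.74 with an estimated correlation). Of them 0 passed (0 adjusted over the list alone). The camera call was lost with the GC content offset (-0.42, adjusted p = 0.244), without both libraries of WT number 2 (0.0668) or 3 (0.0612), and without HOMO CB library 2 (0.111), HOMO CC library 3 (0.0567) or WT CB library 2 (0.0575) or 3 (0.0948).

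In HOMO, 409 genes rose and 495 fell by edgeR, or 586 and 416 with upper-quartile scaling (58.5% higher against 45.2%). With the WT replicate number as a block the total of 904 became 2295, with 1046 higher and 1249 lower. It was 258 and 174 without HOMO CB library 2 or 3, 191 and 225 without HOMO CC library 2 or 3, 1546 without WT CB library 3 and 1586 without WT CC library 3. It was 4452 with only the groups compared, 1662 with DESeq2, 463 against a fold of 1.2, 1742 with Xist as a covariate, and 596 and 3706 without both libraries of WT number 1 or 3. Of the genes called in HOMO, 395 of 409 rises and 478 of 495 falls were also called in the same direction in WT (96.6% of each), against 47.2 and 61.1 for independent lists, and 0 were called in opposite directions. Of the 3965 genes called in WT, 3839 (96.8%) had the same sign in HOMO, with a median ratio of the HOMO to the WT log2 change of 0.7. The slope of the HOMO on the WT log2 changes of these genes, through 0, was 0.42. Selecting genes by their WT call can by itself lower both values. The slope also weighs the largest changes most, and in WT the largest rises followed the macrophage sum. Both values therefore do not show a weaker stage change in HOMO. Across the 8805 genes with an average log2 CPM of at least 3, the stage changes of both genotypes correlated with a Pearson r of 0.869, and genes are not independent replicates. The different numbers of genes called do not show that the stages differed less in HOMO, since with only the groups compared more genes were called in HOMO (4452) than in WT. The interaction, reported with the genotype comparisons, called 0 genes. It had fewer genes with an unadjusted p under 0.05 (434) than expected from chance (830), so its 0 calls do not show that the stage changes were the same.

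**Figure D3:**
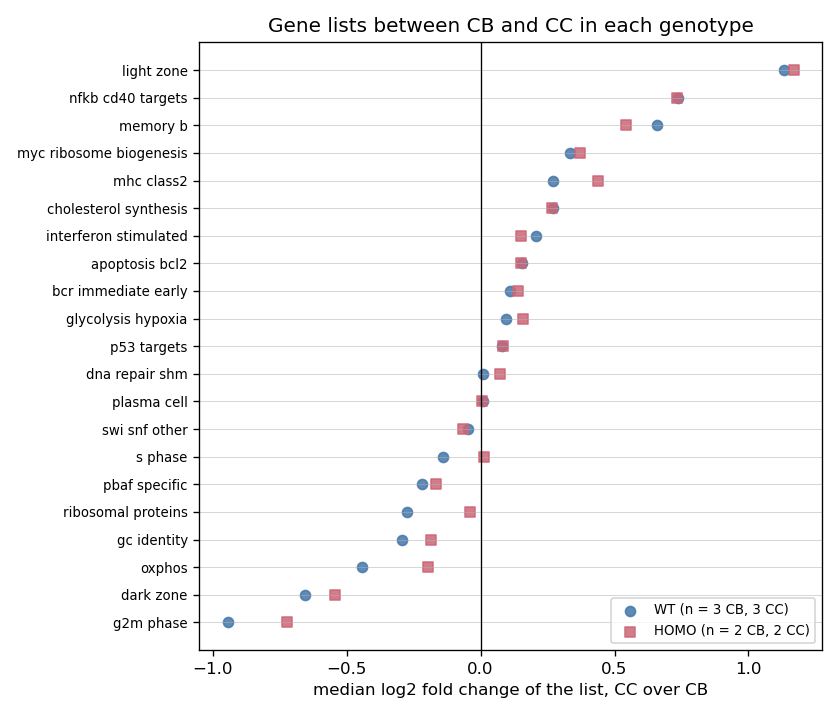
Median log2 change between CC and CB of the 21 lists of biological processes in WT (circles, n = 3 and 3) and HOMO (squares, n = 2 and 2). The light zone list lies at 1.13 and 1.17 and the G2 and M phase list at -0.94 and -0.72. The medians of the other SWI/SNF subunits in WT and of the ribosomal proteins in HOMO change sign with the scaling.

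HOMO was compared with WT within CB to ask which genes differ between the labelled genotypes at that stage. Besides Pbrm1, 3 genes passed, each without overlap between the libraries. Gatm, a creatine synthesis enzyme (ENSMUSG00000027199.14, chromosome 2, 122594467 to 122611303), rose from 42.1 ± 3.44 to 80.6 ± 5.51 CPM (log2 0.94, SE 0.12, edgeR adjusted p = 0.0306, n = 3 and 2). Myo7a, an unconventional myosin (ENSMUSG00000030761.16, chromosome 7, 98051060 to 98119524), fell from 19.3 ± 2.73 to 7.44 ± 0.764 CPM (log2 -1.37, SE 0.16, edgeR adjusted p = 0.0192). Ptpre, a receptor tyrosine phosphatase (ENSMUSG00000041836.10, chromosome 7, 135537481 to 135686293), fell from 10.2 ± 0.806 to 3.77 ± 0.93 CPM (log2 -1.45, SE 0.19, edgeR adjusted p = 0.0306). DESeq2 called 277 genes (137 higher and 140 lower), limma-voom 7, and limma-voom with the WT replicate number as a random block 16. In edgeR 2079 genes (12.5%) had an unadjusted p under 0.05 against 830 from chance. Genes are not independent, and the change in CB followed GC content (Spearman rho -0.667), so this excess does not count genotype changes. The count of 4 was 0 without WT CB library 1, HOMO CB library 2 or 3, or HOMO CC library 2 or 3. It was 1 (Pbrm1) without WT CB library 2 or WT CC library 2, 8 without WT CC library 3 and 1986 without WT CB library 3, and Ptpre alone lost its call without WT CC library 1 (edgeR adjusted p = 0.0679).

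Several lists were shifted downwards together in HOMO CB by camera at its preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.917 for each). Ribosomal protein genes were negative in 76 of 80 cases (median -0.27, camera adjusted p = 1.58e-09), MYC target and ribosome biogenesis genes in 40 of 50 (-0.15, 0.000385) and oxidative phosphorylation genes in 65 of 73 (-0.21, 9.16e-05). Light zone genes were negative in 23 of 27 cases (-0.21, 0.012), immediate early genes in 28 of 30 (-0.41, 0.0192), S phase genes in 41 of 51 (-0.13, 0.0287) and MHC class II genes in 15 of 17 (-0.17, 0.00869). No member of these lists passed by edgeR over all genes, and adjusted over the list alone 2 of the MYC list, 1 light zone gene, 1 immediate early gene and 0 of the others were lower. Egr1 was at 45.5 ± 4.27 CPM in WT CB and 27 ± 2.86 CPM in HOMO CB (log2 -0.75, SE 0.15, edgeR adjusted p = 0.167), Odc1, the ornithine decarboxylase gene, at 173 ± 5.85 and 121 ± 6.98 CPM (-0.51, SE 0.12, 0.213) and the ribosomal protein gene Rps2 at 524 ± 115 and 388 ± 18.4 CPM (-0.43, SE 0.16, 0.339). All 3 passed without WT CB library 3, with edgeR adjusted p of 0.0171, 0.0293 and 0.00386, and over all alternatives the values ranged from 2.8e-05, 0.000285 and 4.08e-05 to 1. The log2 changes then ranged from -0.851 to -0.409 for Egr1, -0.593 to -0.321 for Odc1 and -0.598 to -0.043 for Rps2. That of Rps2 was -0.213 with the GC content offset, -0.219 with Xist as a covariate and -0.043 against WT number 3 alone. The 12 tested neutrophil genes were all higher in HOMO CB (median 3.61, camera adjusted p = 9.16e-05, and adjusted p = 0.917 with an estimated correlation). This lay mostly in HOMO CB library 2, where S100a9 was at 46.2 CPM, against 2.6 CPM in HOMO CB library 3 and 3.88 CPM in WT CB library 3. The neutrophil sum of HOMO CB library 3 (10.65 CPM) was below that of WT CB library 3 (18.42 CPM). Against WT number 3 alone the neutrophil median was 2.32. Across 8802 genes, which are not independent replicates, the change followed GC content with a Spearman rho of -0.667. Without WT CB library 3 the light zone median was -0.08 (camera adjusted p = 0.315) and the immediate early median 0.15 (0.994), and without HOMO CB library 3 the light zone list (0.0549), the S phase list (0.209) and the MHC class II list (0.0828) did not pass. The S phase list also missed without WT CB library 1 (0.205) or 2 (0.432), the oxidative phosphorylation list without WT CB library 2 (0.0956) and the MHC class II list without WT CB library 2 (0.0846). With the GC content offset the light zone (-0.086, 0.0907), immediate early (-0.338, 0.322) and MHC class II lists (-0.099, 0.185) did not pass. Against WT number 3 alone, which was chosen after seeing the data and leaves 1 WT CB library, the medians were 0.07 for ribosomal protein, 0.16 for oxidative phosphorylation and 0.10 for S phase genes. These were opposite to those against all WT libraries. The MYC list (0.004, camera adjusted p = 0.743) and the MHC class II list (-0.002, 0.993) did not pass against WT number 3 alone. The light zone median was -0.30 against that library and -0.051 (0.411) without WT number 3, and the immediate early median -1.15 and 0.198 (0.411).

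HOMO was next compared with WT within CC. No gene passed by edgeR, where the smallest adjusted p was 0.0564 (Pbrm1) and 3142 genes (18.9%) had an unadjusted p under 0.05. Limma-voom called 0 genes and DESeq2 called 816 (359 higher and 457 lower). The edgeR count of 0 was 122 without WT CB library 3 and 2424 without WT CC library 3. Mybl1, a germinal center transcription factor gene, was at 489 ± 16.5 CPM in WT CC and 711 ± 1.81 CPM in HOMO CC (log2 0.54, SE 0.086, edgeR adjusted p = 0.0895, n = 3 and 2). Samd9l, an interferon-stimulated gene, was at 94.5 ± 22.1 and 151 ± 7.44 CPM (0.68, SE 0.15, 0.104), the DNA repair gene Brca1 at 139 ± 2.83 and 182 ± 1.45 CPM (0.38, SE 0.087, 0.105) and Nfkb2 at 166 ± 17 and 122 ± 5.54 CPM (-0.45, SE 0.11, 0.123). All 4 passed without WT CC library 3, with adjusted p of 0.00501, 0.00212, 0.0114 and 0.00913, and Mybl1 (0.0288) and Brca1 (0.0483) also without WT CB library 3. Over all alternatives the adjusted p reached 0.589, 0.741, 0.601 and 0.729 for Mybl1, Samd9l, Brca1 and Nfkb2 at the highest and 6.06e-08, 6.54e-06, 0.000218 and 0.000316 at the lowest. The log2 changes ranged from 0.069 to 0.578, 0.342 to 0.9, 0.303 to 0.428 and -0.515 to -0.138. With the GC content offset they were 0.149 for Mybl1 (adjusted p = 0.589) and -0.154 for Nfkb2 (0.529). With the ribosomal RNA locus share as a covariate they were 0.342 for Samd9l (0.741) and -0.29 for Nfkb2 (0.729). Gatm was at 62.9 ± 6.43 and 109 ± 8.78 CPM, Myo7a at 33.3 ± 2.77 and 13.5 ± 0.383 CPM and Ptpre at 16.8 ± 0.462 and 10.2 ± 0.224 CPM in WT CC and HOMO CC, in the direction of their changes in CB.

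In the list tests, dark zone genes (median 0.16, camera adjusted p = 0.0273), G2 and M phase genes (0.10, 0.00554) and genes of hypermutation, class switching and break repair (0.13, 0.00803, with 22 of 32 positive) were shifted upwards in HOMO CC at the preset correlation. MYC target and ribosome biogenesis genes (-0.12, 0.0416) and immediate early genes (-0.44, 0.0333, with 27 of 30 negative) were shifted downwards. None of these 5 calls held with an estimated correlation (adjusted p = 0.75, 0.791, 0.75, 0.791 and 0.829). Adjusted over the list alone, 1 dark zone and 1 repair gene were higher, 1 MYC list gene was lower and 0 genes of the other 2 lists passed. Without WT CC library 3 the immediate early median was 0.14 (camera adjusted p = 0.824). Without HOMO CC library 2 the immediate early (0.182), repair (0.0517) and MYC lists (0.205) did not pass, and without HOMO CC library 3 neither did the dark zone (0.0514) and G2 and M phase lists (0.163). The MYC list also missed without HOMO CB library 2 (0.0838) or 3 (0.0847) and without WT CC library 1 (0.0677) or 2 (0.073). With the GC content offset the dark zone (0.137, 0.0759), G2 and M phase (0.086, 0.0586), MYC (-0.06, 0.2) and immediate early lists (-0.324, 0.462) did not pass. Against WT number 3 alone, which leaves 1 WT CC library, the MYC median was -0.007 (0.282) and the immediate early median -1.02, and without WT number 3 the latter was 0.044 (0.394).

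Lists of other cells and of mitochondrially encoded genes also differed between HOMO and WT CC at the preset correlation. In each of the 4 lists, the libraries of WT or of HOMO lay far apart from each other in their sums. The macrophage list had a median of -3.91 (20 of 22 negative, camera adjusted p = 2.81e-07; 15 lower adjusted over the list alone, 0 over all genes) and the erythroid list one of -3.22 (8 of 8 negative, 0.00803; 0 adjusted over the list alone). The erythroid call was lost without WT CC library 1 (0.149), where the globin gene Hbb-bs, which shares sequence with Hbb-bt, was at 28.3 CPM against 0.305 and 1.52 CPM in HOMO CC. The mitochondrially encoded genes had a median of -1.43 (12 of 12 negative, 0.000198) and the neutrophil genes one of 3.70 (12 of 12 positive, 0.000313), and the neutrophil call was lost without HOMO CC library 2 (0.0646). Adjusted over the list alone 0 mitochondrial and 0 neutrophil genes passed. None of these 4 calls held with an estimated correlation (adjusted p = 0.75 for each). Against WT number 3 alone, with 1 WT CC library left, the median was -0.42 for macrophage genes (camera adjusted p = 0.00456), -0.42 for erythroid genes (0.434), -0.037 for mitochondrially encoded genes (0.961) and 2.07 for neutrophil genes (0.166). The neutrophil sum of 163.9 CPM in HOMO CC library 2 stood against 25.34 CPM in HOMO CC library 3 and 26.82 CPM in WT CC library 3. Across 8802 genes the change followed GC content with a Spearman rho of -0.59.

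**Figure D4:**
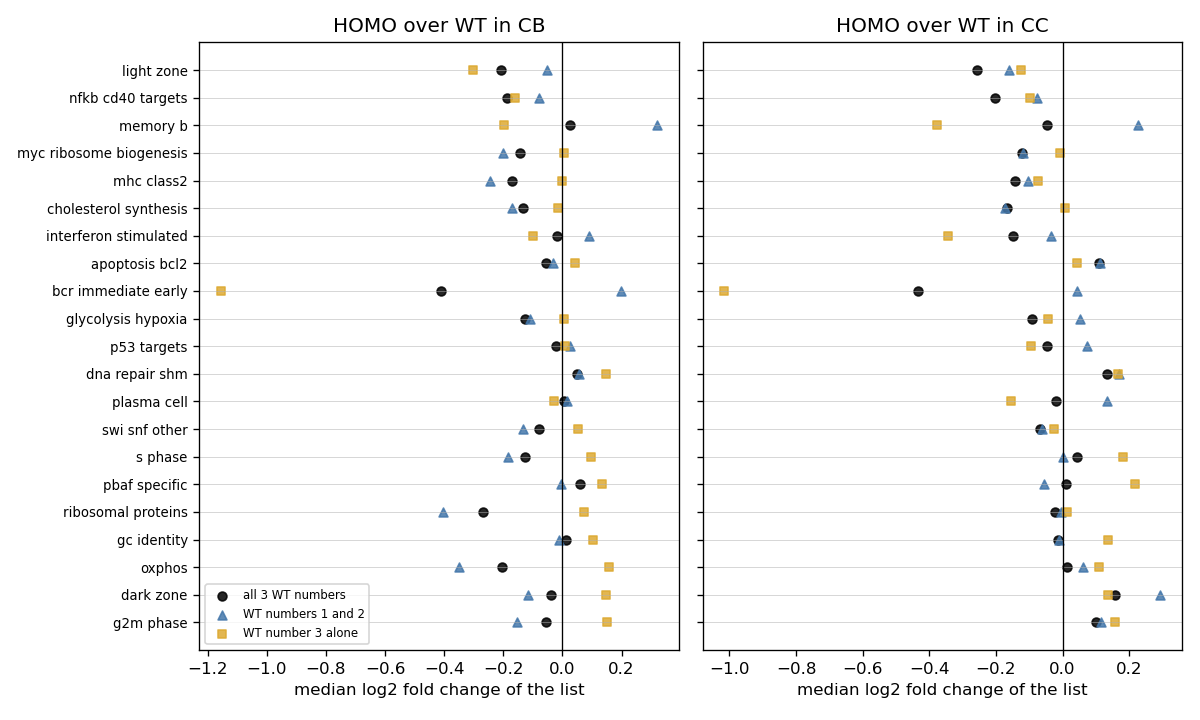
Median log2 change between HOMO and WT of the 21 lists of biological processes in CB (left) and CC (right), against all 3 WT numbers (circles), WT numbers 1 and 2 (triangles) and WT number 3 alone (squares). The immediate early median in CB is -0.41, 0.20 and -1.15 against these 3 sets. With all WT numbers, the dark zone, interferon and p53 medians in CB and the germinal center identity median in CC lie near 0 and change sign with the scaling.

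The genotype changes in CB and CC were then set against each other. Across all 16596 genes tested they correlated with a Pearson r of 0.421 and had the same sign in 70.7% of genes, and across the 8805 genes with an average log2 CPM of at least 3 the values were 0.685 and 75.6%. Both changes followed GC content. With the GC content offset the values were 0.38 and 64% over all genes and 0.528 and 66.4% over the 8805 genes. Over all genes r was 0.269 without HOMO CC library 2 and at least 0.309 without any other single library. CB and CC libraries of the same WT number deviated together, so part of this similarity may come from shared animals or days, and genes are not independent replicates. The interaction, which tests whether the genotype change differed between CC and CB, called 0 genes by edgeR, limma-voom and DESeq2, and 434 genes (2.6%) had an unadjusted p under 0.05 against 830 from chance. The edgeR count was 36 without WT CB library 3 and 5 without WT CC library 3. It was far higher without both libraries of WT number 3 and with no low-count filter, as given with the processing below. The genes with the smallest p were Tspan9, Tmem205, Lgr5 and Rnf144b (edgeR adjusted p = 1 for each). Lgr5 was at 24.7 ± 1.72 and 24.3 ± 1.18 CPM in WT and HOMO CB and at 3.35 ± 0.38 and 5.73 ± 0.448 CPM in WT and HOMO CC, while the group means of the other 3 were at most 3.37 CPM. In WT CC libraries 1, 2 and 3, Tspan9 was at 1.48, 0.88 and 0.562 CPM and Rnf144b at 6.74, 2.33 and 1.05 CPM. This is the order of the macrophage sum, which Tmem205 (0.822, 0.829 and 0.632 CPM) did not have. Of the 32 lists, 7 passed camera in the interaction at the preset correlation and 0 with an estimated correlation or by fry.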

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

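The tests of the interaction were fixed before the data were examined, while the tests of explanations were chosen after seeing the data, with the limits for the GC content and length corrections set before their own results were seen. Camera called a difference between the genotype changes in CC and CB for 7 lists at the preset correlation, and for none with an estimated correlation (adjusted p = 0.84 for each). The interaction median, the genotype change in CC minus that in CB, was 0.256 for ribosomal protein genes (67 of 80 positive, camera adjusted p = 2.08e-10), 0.284 for oxidative phosphorylation genes (63 of 73, 9.52e-10), 0.153 for S phase genes (44 of 51, 8.89e-07) and 0.174 for G2 and M phase genes (48 of 55, 9.01e-06). For dark zone genes it was 0.111 (15 of 15 positive, camera adjusted p = 0.00532), 0.126 (0.0754) without WT number 1, and -0.008 (0.625) against WT number 3 alone. For mitochondrially encoded genes it was -0.702 (12 of 12 negative, camera adjusted p = 0.0106), a call lost with the GC content offset (-0.697, 0.122) and without WT number 1 (-0.34, 0.245), WT CB library 3 (-0.56, adjusted p = 0.368), HOMO CB library 2 (-0.50, 0.0743) or WT CC library 1 (-0.18, 0.756), and against WT number 3 alone (0.071, 0.323). For macrophage genes it was -2.969 (20 of 22 negative, camera adjusted p = 3.05e-06), and -0.076 (0.778) against WT number 3 alone. These shifts lie in the median of a list, while edgeR called 0 genes in the interaction, where 434 had an unadjusted p under 0.05 and limma-voom and DESeq2 also called 0.

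The macrophage shift lay in WT CC libraries 1 and 2. Genotype as the whole cause would make the WT CC libraries alike, and the median ratio of library 1 to library 3 over the listed genes was 20, which argues against it. Macrophages in some WT CC libraries would bring all their transcripts, and 81.8% of the listed genes (18 of 22) were at least 3 times as high in WT CC library 1 as in every CB library, with ratios of library 1 to library 2 between 2.56 and 5.55 over these 18 (median 3.84). Csf1r was at 196, 40.8 and 7.02 CPM and Axl at 185, 41.3 and 6.18 CPM in WT CC libraries 1, 2 and 3, while Lyz2, Cd68, Itgam and Apoe were not raised in this way (Apoe 356, 308 and 252 CPM, Lyz2 4.93, 4.45 and 7.58 CPM). Macrophages with low Lyz2 in 2 WT CC libraries are a candidate explanation, although PNA enrichment is meant to leave such cells out. The raised sum of these genes prompted the test of their share, so that share is not separate evidence.

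The ribosomal protein, oxidative phosphorylation, S phase and G2 and M phase shifts were weighed against a trend with GC content and length and against genotype as the whole cause. Across genes with an average log2 CPM of at least 3, the interaction had a Spearman rho of -0.017 with GC content and -0.277 with length. The offset could therefore act here mainly through length. With the GC content and length offset the S phase median was 0.119 (77.8% left, camera adjusted p = 1.74e-07) and 82.2% of the G2 and M phase median was left (3.58e-06), which argues against that trend as their whole cause. The ribosomal protein median was 0.127 with the offset, 49.6% of its value, against 51.1% for oxidative phosphorylation. Both calls held (camera adjusted p = 6.38e-06 and 1.68e-05). The limit set beforehand applied to the smaller of both medians, that of ribosomal protein genes, which lay just under it. By that rule the prediction for the trend as a cause was met. After the values were seen the rule was changed to ask this of both lists, and by the changed rule the test cannot decide. The trend may be a cause of part of these shifts. Against WT number 3 alone the median was -0.076 for ribosomal protein (camera adjusted p = 0.000149), -0.066 for oxidative phosphorylation (0.0186), -0.013 for G2 and M phase (0.571) and 0.077 for S phase genes (0.000675). Genotype and differences between the WT numbers cannot be told apart for these 4 lists, because that comparison leaves 1 WT library in each fraction.

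WT number 3 stood apart from WT numbers 1 and 2. Without it, edgeR called 4895 genes between HOMO and WT in CB and 5035 in CC, against 4 and 0 with it. With the GC content offset 62.6% of the sum without it was left (6213 of 9930), which argues against the GC content trend as the whole cause of these calls. The calls left can come from genotype, and these fits hold no library of WT number 3. They therefore do not show whether the GC content trend sets WT number 3 apart. X- and Y-linked genes made up 2.75% of the genes called without WT number 3 (203 of 7372) and 2.8% of the 16088 tested, a ratio of 0.98. So many of the tested genes were called that the ratio could not have reached the limit set for the sex mix as a cause. That test therefore cannot decide about the sex mix of the cells. An effect of the sex of the animals was not settled, their age and the day of preparation were not tested, and these stay open. Genotype gives no explanation, since WT number 3 shares it with the other WT numbers.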

How the results depend on the processing

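Of the named genes reported here, 302 results under the alternatives gave 9729 values, of which 9003 kept their side of the threshold, 356 lost the call and 370 gained one. The sign turned in 68 of the 9003, which passed neither with all libraries nor under the alternative, and in 0 of the others. Of the list medians (160 results, 3072 values) 2672 kept their side, 207 lost the call and 151 gained one. The sign turned in 247 of the 2672, which passed neither way, and in 42 others, where the list passed with all libraries or under the alternative. Another scaling, counted apart, turned the sign of 10 medians of lists that did not pass. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the others. The causes were not tested unless a setting removes libraries or genes.

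The number of genes changed between HOMO and WT in CB (4) was 277 with DESeq2, 7 with limma-voom, 590 with no low-count filter, 0 with only the groups compared, 2 with a fold of 1.2 as the null, 16 with a random replicate block of the WT numbers and 2 with Xist as a covariate. It was 0 without WT number 1, 0 without number 2, 4895 without number 3, 671 without numbers 1 and 2, 1 without WT CC libraries 1 and 2, 2660 with the GC content offset without number 3, and 0 to 1986 without single libraries. In CC (0) it was 1 with upper-quartile factors, 816 with DESeq2, 1314 with no filter, 2 with a stricter filter, 2 with the GC content offset, 4 with GC content and length, 3 with Xist, 5035 without number 3, 652 without numbers 1 and 2, 3553 with the GC content offset without number 3, and 0 to 2424 without single libraries. The interaction (0) gave 154 with no filter, 1445 without number 3, 1 without numbers 1 and 2, 1536 with the GC content offset without number 3, and 0 to 36 without single libraries.

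For CC against CB in WT (3965) the count was 2340 with only the groups compared, 2134 with the fold of 1.2, 656 with the ribosomal RNA locus share, 1010, 1243 and 7404 without WT numbers 1, 2 and 3, 2421 without numbers 1 and 2, 858 without WT CC libraries 1 and 2, 7226 with the GC content offset without number 3, and 2099 to 5315 without single libraries. In HOMO (904) it was 1662 with DESeq2, 1475 with no filter, 4452 with only the groups compared, 463 with the fold of 1.2, 2295 with the replicate block, 1844 with the block and the GC content offset, 1742 with Xist, 596 and 3706 without numbers 1 and 3, 4459 without numbers 1 and 2, 1366 without WT CC libraries 1 and 2, 3232 with the GC content offset without number 3, and 174 to 1586 without single libraries. The log2 change of Pbrm1 in CB (-0.875) was -0.863 with only the groups compared and without number 1, -0.885 without number 2, and -0.921 to -0.802 without single libraries. In CC (-0.684) it was -0.678 with DESeq2, -0.66 with no filter, -0.692 with a stricter filter, -0.897 with the GC content offset, -0.882 with GC content and length, -0.697 with Xist, -0.632 without number 3, -0.704 without numbers 1 and 2, -0.925 with the GC content offset without number 3, and -0.696 to -0.651 without single libraries.

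The number of lists passing camera was 8 in HOMO against WT in CB (0 with an estimated correlation, 0 by fry, 14 without numbers 1 and 2, 5 to 13 without single libraries), 9 in CC (0, 0, 17, and 5 to 12) and 7 in the interaction (0, 0, 0 with the block and an estimated correlation, and 6 to 13). It was 15 in WT between fractions (3 with an estimated correlation, 2 with the block also) and 17 in HOMO (2 and 2). The similarity of the genotype changes (r = 0.421) was 0.38 with the GC content offset, 0.685 over genes with an average log2 CPM of at least 3, and 0.269 to 0.446 without single libraries. Without numbers 1 and 2 the sign turned for the S phase (0.098), ribosomal protein (0.073), oxidative phosphorylation (0.158), MYC (0.004), dark zone (0.147), G2 and M phase (0.152), memory B cell (-0.198) and T cell (-0.501) medians in HOMO against WT in CB. It turned for the germinal center identity (0.136), naive follicular B cell (-0.081) and T cell (-0.489) medians in CC, and for the ribosomal protein (0.051) and repair (-0.015) medians between fractions in WT. In the interaction it turned for the ribosomal protein (-0.076), oxidative phosphorylation (-0.066), dark zone (-0.008), G2 and M phase (-0.013) and mitochondrial (0.071) medians. Without number 3 it turned for the immediate early median in CB (0.198) and for the immediate early (0.044), plasma cell (0.134) and memory B cell (0.227) medians in CC. The PBAF median turned with the GC content offset in CB (-0.033) and CC (-0.114) and with GC content and length in CB (-0.016). Without single libraries the immediate early median ranged from -0.623 to 0.147 in CB, -0.68 to 0.144 in CC, -0.538 to 0.321 in the interaction, -0.584 to 1.109 between fractions in WT and -0.038 to 0.312 in HOMO. The memory B cell median ranged from -0.241 to 0.21 in CC and -0.18 to 0.151 in the interaction, the T cell median from -1.55 to 1.72 in the interaction, the plasma cell and repair medians from -0.102 to 0.096 and -0.035 to 0.045 between fractions in WT, and the neutrophil median from -2.324 to 3.134 in HOMO.

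With the replicate block of the WT numbers, the edgeR calls that changed were those of Arid2 (adjusted p = 0.0219) and Phf10 (0.0315) between fractions in WT, and of Atp5f1 (0.0321), Sdhb (0.0372) and Rps13 (0.0498) in HOMO. The camera calls that changed were those of naive follicular B cell genes in the interaction (0.0151), erythroid (0.0132) and platelet genes (0.0327) in WT, other SWI/SNF subunits (0.0485) and T cell genes (0.00416) in HOMO, and dark zone genes in WT with an estimated correlation. The random block of the WT numbers in limma-voom lost the calls of C6 (adjusted p = 0.158), Fcna (0.121), Gfra2 (0.213), Itgad (0.212), Mertk (0.25), Paqr9 (0.162), Ptprm (0.208) and Wdfy3 (0.254) in WT and of Apex1, Gbp3, Mif, Mvd and Pfkfb3 in HOMO (0.0575 to 0.0691). With the preset correlation of camera and in the tests of genes, the blocks changed no other call of a gene or list reported here. Of the planned blocks, the number across genotypes and the number within HOMO were not run, because the HOMO columns carry no number of the labels. What depth alone limits was not tested. In the simulated counts changed genes were drawn only above a minimum level, and the median of the genes drawn from was 37.9 CPM. A fold of 2 was recovered for 58.1% of changed genes below this median and 88.9% of the others in HOMO against WT in CB. In CC the shares were 57.1% and 100%.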

Other observations

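The tests of the genes around Pbrm1, of the WT numbers and of the other splits were chosen after the results were seen. Several gene groups moved both ways between CC and CB. Among BCL2 family and apoptosis genes 8 of 28 rose and 5 fell in WT CC (8 and 6 adjusted over the list alone, camera adjusted p = 0.214). In HOMO CC 5 rose and 1 fell (8 and 2 adjusted over the list alone), and the list passed camera upwards (adjusted p = 0.0158, and adjusted p = 0.18 with an estimated correlation). That call was lost without both libraries of WT number 3 (median 0.149, camera adjusted p = 0.0524). In WT CC the survival gene Bcl2l1 rose from 18.3 to 36.1 CPM (log2 0.98, SE 0.14, edgeR adjusted p = 0.000809). Bcl2l11, which promotes cell death, fell there from 85.6 to 46 CPM (log2 -0.90, SE 0.16, edgeR adjusted p = 0.0026). Among memory B cell genes 11 of 28 rose and 3 fell in WT (11 and 4 adjusted over the list alone), with a median of 0.66 and camera adjusted p = 0.0164 (adjusted p = 0.591 with an estimated correlation), a call lost without WT CC library 3 (0.04, adjusted p = 0.55). In HOMO 6 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.00372, and adjusted p = 0.485 with an estimated correlation). The transcription factor gene Zeb2 rose by log2 1.71 (SE 0.15) in WT and 1.37 in HOMO, and Fcer2a, the low-affinity IgE receptor gene, by 1.71 and 1.88.

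Among plasma cell genes 2 of 32 rose and 7 fell in WT CC (2 and 7 adjusted over the list alone; camera adjusted p = 0.272, and 0.0288 without WT CC library 3). Jchain, the joining chain of secreted antibodies, fell from 514 to 184 CPM (edgeR adjusted p = 0.000617), and Derl3, a gene of protein quality control, rose by log2 1.32 in WT and 1.31 in HOMO. Among p53 targets 3 of 30 rose and 7 fell in WT (5 and 7 adjusted over the list alone; camera adjusted p = 0.284), with the ribonucleotide reductase gene Rrm2b going from 142 to 53.9 CPM. Among SWI/SNF subunits that are not specific to PBAF, several of which PBAF shares, 1 of 23 rose, Smarca2 (log2 0.75, edgeR adjusted p = 0.0027), and 6 fell (1 and 7 adjusted over the list alone), with Smarca4 and Bcl7a (log2 -0.65) among these. The camera test of this list gave adjusted p = 0.199, and 0.0257 without WT CB library 3, and its median of -0.05 changed sign with the scaling. Smarca4, whose product and that of Smarca2 are alternative ATPases of the complex, fell in HOMO as well (log2 -1.08, SE 0.14).

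S phase genes fell in 12 of 51 cases in WT CC and rose in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 0.0125, and adjusted p = 0.703 with an estimated correlation). That call was lost without WT CB library 1 (0.0563) or 2 (0.0956) or WT CC library 3 (0.18), and in HOMO 1 fell and 0 rose (camera adjusted p = 0.821). Cholesterol synthesis genes rose in 10 of 24 cases in WT CC and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.0175, and adjusted p = 0.647 with an estimated correlation), a call lost without WT CB library 3 (0.181) or WT CC library 2 (0.0701). In HOMO 1 rose and 0 fell (0 adjusted over the list alone; camera adjusted p = 0.00706, and adjusted p = 0.595 with an estimated correlation). Genes of glycolysis and hypoxia rose in 7 of 36 cases and fell in 4 in WT (camera adjusted p = 0.187), and rose in 3 and fell in 0 in HOMO (camera adjusted p = 0.0227, and adjusted p = 0.18 with an estimated correlation). Their median in HOMO was 0.157. The camera call was lost with the GC content offset (0.098, adjusted p = 0.0975) and with that for GC content and length (0.123, 0.107). Immediate early genes rose in 6 of 30 cases and fell in 2 in WT (median 0.11; camera adjusted p = 0.0467, and adjusted p = 0.723 with an estimated correlation). Their median was -0.18, -0.22 and -0.58 without WT CB library 1, WT CB library 2 or WT CC library 3, where the call was lost (0.119, 0.186 and 0.933). It was also lost with the GC content offset (median 0.094, camera adjusted p = 0.323) and without both libraries of WT number 3 (0.009, 0.181). In HOMO 4 rose and 1 fell (median 0.14; camera adjusted p = 0.0158, and adjusted p = 0.74 with an estimated correlation). That call was lost without HOMO CB library 2 (0.0503) or WT CC library 3 (0.0551), and the median was -0.038 without HOMO CC library 3. With the GC content offset the immediate early median in HOMO was 0.179 and the list did not pass (camera adjusted p = 0.174). Genes of germinal center identity fell in 7 of 27 cases and rose in 2 in HOMO (camera adjusted p = 0.00258, and adjusted p = 0.081 with an estimated correlation).

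A hypothesis was that genes close to Pbrm1 on chromosome 14 differ between HOMO and WT through the targeted locus or DNA linked to it. Of 70 tested genes within 5 Mb of Pbrm1, 7 (10%) had an edgeR p under 0.01 in CB, against 3.36% elsewhere, and 2.31% of 15087 windows of as many neighbouring genes held as many. In CC the number was 6, as many as in 29.62% of windows. With the GC content offset it was 5 in CB (1.74% of windows) and 7 in CC (5.07%). The 7 genes in CB were Fam208a, Mettl6, Colq, Ncoa4, Wdfy4, Shld2 and Bmpr1a, of which Wdfy4 was at 734 CPM in WT and 1170 CPM in HOMO and Bmpr1a at 15.6 and 4.5 CPM, and none passed adjustment over all genes. A linked or local effect in CB may explain part of this, but no genotype of the flanking DNA was analysed here.

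Of 15684 genes tested in both, 4892 were called by edgeR between HOMO and WT numbers 1 and 2 in CB and 662 between HOMO and WT number 3, which has 1 library per fraction. In CC the numbers were 4895 and 648. Called in both with the same sign were 302 genes in CB and 348 in CC, against 103.3 and 101.9 for independent lists and 0 in each of 10 simulations without a genotype effect. Both comparisons share the HOMO libraries, from which part of the excess may come, and these libraries are too few to be split. The simulations held neither a GC content trend nor a difference between WT numbers, so they do not show what these would give. Of the genes called against WT numbers 1 and 2, 64.4% in CB and 75.7% in CC kept their sign against WT number 3. The slope of the log2 changes against WT number 3 on those against numbers 1 and 2, through 0, was 0.1 in CB and 0.25 in CC. The log2 change against both sets was -1.46 and -1.18 for Myo7a, 0.98 and 0.88 for Gatm and -0.71 and -0.77 for Egr1 in CB, and 0.58 and 0.55 for Mybl1 and -0.63 and -0.70 for Pbrm1 in CC, genes that were picked out after their values were seen. None of these fits used the GC content offset, with which the change of Mybl1 against all WT numbers was far smaller, as given above. WT CC library 3 also differed from HOMO CC in its GC content trend (Spearman rho 0.152 against -0.173 and -0.222). Calls or changes shared by both sets therefore do not separate genotype from that trend.

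The 6 WT libraries can be split into groups of 3 and 3 in 10 ways, which are too few for a share under 0.05. The real split gave 3965 genes between CC and CB, and the highest of the other splits gave 0, so 1 of the 10 gave as many. Every other split puts CB and CC libraries into both of its groups, so the difference between fractions adds to the spread within them. Few calls were therefore likely in the other splits in advance, and no conclusion is drawn from this comparison. The real split was 1 of 4 that part all 3 pairs of WT numbers, and the other 6 part 1 pair.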
